A study of Homo sapiens with 4 samples.

How the data were processed

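RNA from HCT116 cells was measured on 4 arrays, 2 from cells held at 1% oxygen and 2 from cells held at 21% oxygen for 72 h after 24 h without serum. Biotin-labelled cRNA was prepared from 6 µg of total RNA, per the labels' protocols. The values are intensities deposited by the authors, 1 per probe set, on a linear scale and made with MAS5, per the submitters' processing notes; its version is not given in the sources used here. The mean of each array without the lowest and highest 2% of values was 499.9 on all 4 arrays, so that each array appears to have been scaled to a common trimmed mean. Such scaling fixes the mean of an array, so a shift shared by most genes is not seen and directions are relative to the other genes. Detection calls were not used here. No 2 arrays shared more than 1 identical value, so none was counted as a duplicate.

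Samples were grouped by the oxygen level in the labels. Probe sets were named through a table of the platform annotation. Of 54675 probe sets, 62 were controls, 41091 were listed for 1 gene, 1801 for several genes and 11721 for none, and probe sets with several genes were not used. These covered 19777 genes, of which 19735 were matched by gene identifier to a RefSeq gene table for current symbols. For each gene the probe set with the highest mean signal over the 4 arrays was taken, and a gene was tested if that mean was at or above 97.4, the median of all probe set means, which left 12636 genes. Of 2757 called genes with further probe sets past the filter, 594 had at least 1 with the opposite sign. The signal was taken as log2(signal + 23.7), where 23.7 is the 25th percentile of all values. No further normalization was applied. Oxygen groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over the genes tested and calls at an adjusted p under 0.05. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

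Gene lists were tested with limma's camera with a preset correlation of 0.01, two-sided, adjusted over the 19 lists with 5 or more tested members. Of these, 13 passed, 6 higher and 7 lower. With an estimated correlation 0 passed, and 14 passed with fry, which does not compare a list with other genes. The test with an estimated correlation has few residual degrees of freedom with so few arrays, and little power. Failing it therefore does not show that correlation accounts for a result. The estimated correlation was -0.01 for mitosis and -0.04 for DNA repair, under the preset, yet both had adjusted p = 0.188. For the serum response list it was 0.0081. In every other list that passed, the estimate lay above the preset, from 0.10 for interferon response to 0.80 for cholesterol synthesis. It was 0.26 for HIF targets and 0.19 for p53 targets. For those lists the preset assumes less correlation than was estimated, so the preset p-values may be too small. The 21 lists held 457 genes, of which 360 were tested and 1 (ATF3) stood in 2 lists; 39 had no probe set listed for that gene alone and were not analysed here. The genes named in the text follow a rule: the 10 largest increases and the 10 largest decreases among called genes whose hypoxia values both lay on the same side of both normoxia values, a set of 11 hypoxia genes of which 9 were tested, and of each list up to 4 called members with the largest change or, where none was called, up to 2 with the smallest p. Other genes that are named were chosen after their values were seen, which applies to the minority members of a list and to the genes of the closing section. The grouping, tests, lists, naming rule and alternative settings were fixed before the data were examined.

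On simulated data for this comparison (12636 genes, 200 changed, variances drawn from the fitted prior), the fit recovered 1 of 67 genes changed 1.5-fold (1.49%), 7 of 67 changed 2-fold (10.4%) and 40 of 66 changed 4-fold (60.6%). It made 2 false calls among 50, and 1 call when no gene was changed. Recovery after Benjamini-Hochberg adjustment depends on the share of changed genes. The data had 4803 called genes, so the rates for 200 changed genes do not give the power of this comparison. A list of 30 genes shifted by 0.5 on the log2 scale gave a camera p of 6.38e-16, and 9 of 200 unshifted lists had p under 0.05. Genes were drawn independently there, so these values do not show how often lists of correlated genes pass falsely. A first version of this simulation, with variances taken as means of signal bins, fell short of the recovery of 4-fold changes required of it; the variance model was then replaced and that requirement dropped.

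The alternative settings fixed in this way were a replicate block for the letters A and B, other pseudocounts, quantile normalization, scaling to the 75th percentile, other filters, the mean of a gene's probe sets, all probe sets, other variance models and thresholds, other set tests, and leaving out each array in turn. Several choices came after results had been seen. Scaling to the hybridization controls and quantile normalization with a replicate block were added. Under the alternatives the probe set of a gene and the filter were at first chosen again on each setting's own values; after CD44 had been seen to change sign that way, both were held as chosen on the deposited values, and the earlier way is reported as a further alternative. For the closing section 10 further groups, 5 lists and 5 gene families, were examined.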

Results

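Gene expression was measured in HCT116 cells, an established human colon cancer line, that had been kept without serum for 24 h and then held for 72 h at 1% oxygen (hypoxia) or at 21% oxygen (normoxia). Each group held 2 arrays, given as exp A and exp B in the labels of both groups, and the arrays held 54675 probe sets. The labels do not say whether A and B were separate cultures, nor whether arrays of 1 letter share a day or a culture, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision. Values are MAS5 signals, given as mean ± SD with n = 2 arrays per group. Log2 differences are hypoxia minus normoxia on the log2(signal + 23.7) scale, which understates the change of genes with low signal.

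Called higher in hypoxia were 29 of 33 tested targets of hypoxia-inducible factors (HIF), 14 of 17 glycolysis genes, with 3 lower, 14 of 16 cholesterol synthesis genes, with 1 lower, and 16 of 21 serum response and immediate early genes. Called lower were 29 of 31 DNA replication genes, 25 of 30 mitosis genes, 16 of 23 DNA repair genes, 11 of 17 interferon response genes and 13 of 18 ribosome biogenesis genes, with 1 higher. Each of these lists passed camera with a preset correlation, and none passed with an estimated correlation (adjusted p = 0.188 to adjusted p = 0.360). The test with an estimated correlation has little power with so few arrays, here and for each list below, so it cannot decide. Among single genes, the chemokine receptor CXCR4 rose from 50.7 ± 45.9 to 5906 ± 3495, and ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose from 134 ± 72.6 to 10517 ± 3249.9. The interferon-induced gene IFIT1 fell from 5174 ± 867 to 238 ± 173, and PES1, which acts in maturation of the large ribosomal subunit, fell from 1699 ± 98.1 to 53.4 ± 37.6.

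Of 12636 genes tested with limma, 4803 (38.0%) were called at a Benjamini-Hochberg adjusted p under 0.05, 1927 higher and 2876 lower in hypoxia. At least a 2-fold difference was reached by 1221 of the higher and 2046 of the lower genes, and an 8-fold difference by 50 and 132. In all 4803 called genes both hypoxia values lay on the same side of both normoxia values, a pattern found in 72.0% of tested genes where chance gives 33.3%. Among called genes this follows largely from the call itself, so it is no separate support for the calls. Leaving out either normoxia array lowered the number of called genes, and leaving out either hypoxia array raised it. A fit without a normoxia array takes its spread from the hypoxia arrays alone. The median SD on the log2 scale was 0.27 in hypoxia against 0.15 in normoxia. A call lost in this way therefore need not depend on the values of the array left out. The called genes split 40.1% higher to 59.9% lower. Scaling each array to its 75th percentile moved the median of all genes by 0.14 and gave 2373 higher and 2405 lower (49.7% higher). Scaling to the hybridization controls, a setting chosen after seeing the data, moved that median by -1.37 and gave 52 higher and 5514 lower. Counts of called genes under that scaling, here and below, rest largely on a shift shared by all genes of an array. Directions below are therefore relative to the median gene, whose log2 difference was -0.03.

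The 10 largest increases among called genes were those of CXCR4 (log2 difference 6.33 ± 0.51 SE, adjusted p = 7.67e-05), ANGPTL4 (6.11 ± 0.34, 2.40e-05), ANKRD37 (5.02 ± 0.25), the glucose transporter gene SLC2A3 (4.39 ± 0.61), TMEM158 (4.30 ± 0.18), the lysyl oxidase family gene LOXL2 (4.27 ± 0.19), the growth factor gene PDGFA (4.21 ± 0.19), LEMD1 (4.19 ± 0.26), the interleukin-1 receptor subunit gene IL1RAP (4.04 ± 0.24) and NDRG1 (4.02 ± 0.19). TMEM158 rose from 1569.9 ± 292 to 31042 ± 51.7 and NDRG1 rose from 3201 ± 563 to 52121 ± 5838. The normoxia mean of 3 of the 10 lay under 121, the highest signal of a Bacillus control probe set in normoxia, so their folds rest on a value near background. SLC2A3 differed widely between the hypoxia arrays, and its log2 difference without 1 array ranged from 3.28 to 5.50. Its probe set carries the suffix Affymetrix gives to sets that can cross-hybridize, as do those of PFKL, FOXM1, GDF15, CXCL8, FN1 and CD44 below. For CXCR4 the range was 5.66 to 7.01.

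The 10 largest decreases were those of BORCS7 (-5.42 ± 0.47, from 6331 ± 291 to 153 ± 136), PES1 (-4.57 ± 0.42), IFIT1 (-4.48 ± 0.41), HERC6 (-4.41 ± 0.58), IFI6 (-4.37 ± 0.24), SLC43A3 (-4.36 ± 0.52), DTL (-4.31 ± 0.79), the kisspeptin receptor gene KISS1R (-4.26 ± 0.43), RPP40, which encodes a ribonuclease P subunit (-4.23 ± 0.28), and LOC103344931 (-4.19 ± 0.53). IFIT1, HERC6 and IFI6 are interferon-induced, and DTL encodes a substrate adaptor of a ubiquitin ligase active in S phase. The hypoxia mean of 9 of the 10 lay under 305, the highest Bacillus control signal in hypoxia. Across all called genes, 783 of the lower genes had a hypoxia mean under that value and 143 of the higher genes had a normoxia mean under 121. Each value is the highest control on 1 array. It was 305 on hypoxia A against 226 on hypoxia B, and 121 on normoxia B against 45.7 on normoxia A. Since the values are unlike, the 783 and the 143 cannot be compared with each other. In 56 of the higher and 0 of the lower genes the normoxia mean lay under 121 and the hypoxia mean under 305. The filter on the mean over all 4 arrays leaves a lower gene little room to do so. The 0 therefore says nothing about the reliability of the decreases. HERC6 lost its call without normoxia A (-4.26, adjusted p = 0.0740), and LOC103344931 did so when the probe sets were chosen again (-4.11, adjusted p = 0.0545). Without 1 hypoxia array the log2 difference of DTL ranged from -5.85 to -2.78, that of BORCS7 from -6.29 to -4.54, that of KISS1R from -5.04 to -3.48 and that of IFIT1 from -5.21 to -3.75.

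**Figure D1:**
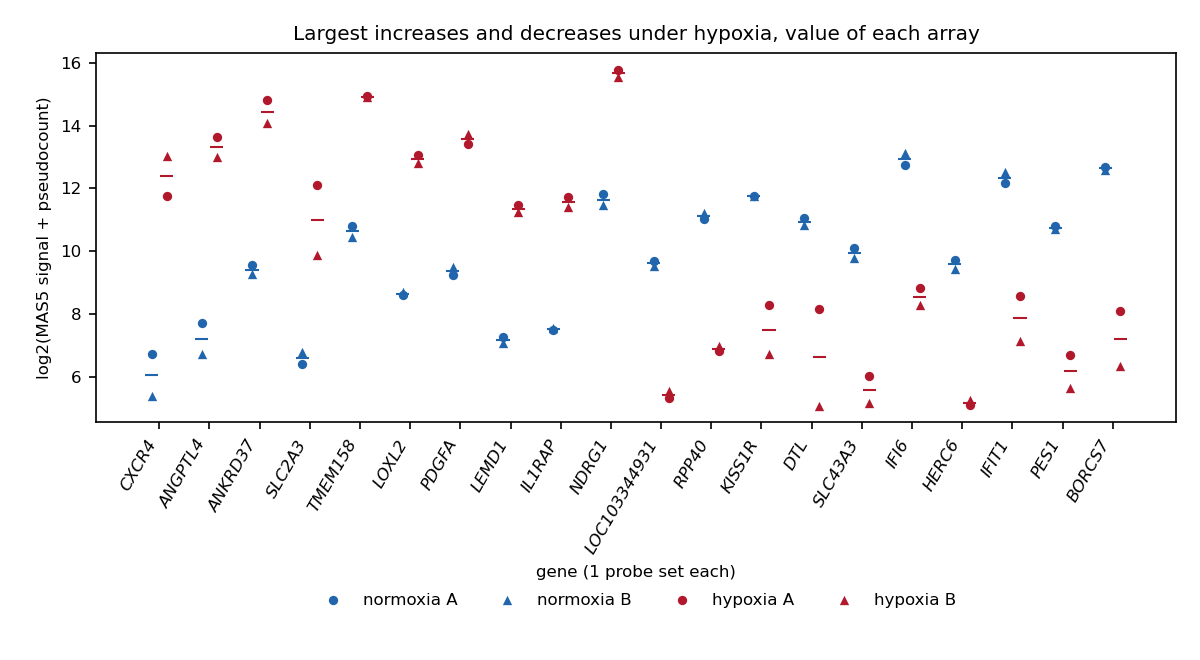
Log2(MAS5 signal + pseudocount) of the 10 genes with the largest increase and the 10 with the largest decrease under hypoxia, with 1 probe set per gene on the horizontal axis. Circles are arrays A, triangles arrays B, and bars the mean of a group; in each gene both hypoxia arrays lie on the same side of both normoxia arrays.

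The HIF target list held 33 tested genes. Of these, 29 rose, 0 fell and 4 were not called, and adjusted over the list alone 30 rose and 0 fell. Besides ANGPTL4, ANKRD37, LOXL2 and NDRG1, the oxygen-sensing prolyl hydroxylase gene EGLN3 rose from 135 ± 59.5 to 2062 ± 338 (log2 difference 3.76 ± 0.33 SE, adjusted p = 1.08e-04). VEGFA, which encodes an angiogenic growth factor, rose from 4016 ± 671 to 17279.5 ± 2973 (log2 difference 2.10 ± 0.19 SE, adjusted p = 1.21e-04). The glucose transporter gene SLC2A1 rose from 975 ± 34.9 to 4183 ± 110.1 (log2 difference 2.08 ± 0.17 SE), and ADM, the adrenomedullin gene, rose from 7662 ± 1451 to 34052 ± 14670.5 (2.09 ± 0.28 SE). The list median was 2.03. Scaled to the hybridization controls it was 0.57, with 9 genes called higher and 1 lower, and lay 1.97 above the median of all genes there. The list passed camera at adjusted p = 3.43e-18 with the preset correlation of 0.01, and had adjusted p = 0.300 with an estimated correlation.

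EPAS1, the gene of the HIF-2 alpha subunit, rose from 2805 ± 231 to 10842 ± 1397 (log2 difference 1.94 ± 0.17 SE, adjusted p = 1.08e-04), while HIF1A, the gene of the HIF-1 alpha subunit, fell from 9626 ± 22.2 to 6789 ± 679.6 (log2 difference -0.51 ± 0.16 SE, adjusted p = 0.0365). The call of HIF1A was lost without normoxia A (-0.50, adjusted p = 0.161), normoxia B (-0.51, adjusted p = 0.151) or hypoxia B (-0.40, adjusted p = 0.0742), and overall in 10 of its 20 alternatives, among them scaling to the 75th percentile (-0.36, adjusted p = 0.119). BNIP3, a mitophagy receptor gene, rose from 4321 ± 996 to 6783 ± 232 (log2 difference 0.67 ± 0.19 SE, adjusted p = 0.0235), a call lost without normoxia B (0.43, adjusted p = 0.254), with a second probe set at 1.17. PDK1, whose product inhibits pyruvate dehydrogenase, was not called, from 1905 ± 622 to 2767 ± 1828 (log2 difference 0.40, adjusted p = 0.478), while 2 other probe sets of PDK1 had log2 differences of 0.93 and 1.25. Its difference was 0.79 between the A arrays and 0.01 between the B arrays, -0.33 without hypoxia A and 1.12 without hypoxia B, where it passed (adjusted p = 0.00171).

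All 17 tested glycolysis genes were called, 14 higher and 3 lower, with the same counts adjusted over the list alone. Besides SLC2A3, the hexokinase gene HK2 rose from 1712 ± 87.4 to 15267 ± 3875 (log2 difference 3.12 ± 0.20 SE, adjusted p = 3.86e-05), the enolase gene ENO2 rose from 1058 ± 191 to 8383 ± 3902 (log2 difference 2.89 ± 0.30 SE, adjusted p = 1.89e-04), and the aldolase gene ALDOC rose from 3630.3 ± 385 to 21383 ± 4779 (log2 difference 2.54 ± 0.20 SE, adjusted p = 6.61e-05). The lower genes were PFKM (-1.79) and PFKL (-1.07), which encode phosphofructokinase subunits, and TPI1 (-0.90), the triosephosphate isomerase gene; these 3 were named after their values were seen. A second probe set of HK2 went the other way, with a log2 difference of -1.33. The median over tested members was 1.23, or 0.64 under quantile normalization and -0.23 when scaled to the hybridization controls, the latter with 2 genes called higher and 3 lower and 1.17 above the median of all genes there. Camera gave adjusted p = 6.49e-06, and adjusted p = 0.319 with an estimated correlation.

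Of 25 genes of oxidative phosphorylation and the citrate cycle, 12 fell, 1 rose and 12 were not called, and adjusted over the list alone 15 fell and 2 rose. The complex I genes NDUFS3 and NDUFV1 fell from 6003 ± 129.7 to 1581 ± 196 (log2 difference -1.91 ± 0.17 SE) and from 3883 ± 129 to 1146 ± 314 (-1.77 ± 0.22 SE). CYC1, a complex III gene, and SDHC, a complex II gene, had log2 differences of -1.27 and -1.26. The gene that rose was CYCS (cytochrome c, 0.64), with other probe sets at -0.33 and 0.32. Over the list the median was -0.48, or -0.74 under quantile normalization, with camera adjusted p = 0.00570, and adjusted p = 0.399 with an estimated correlation. Without normoxia B the number that fell was 6. The number that rose was 0 without hypoxia A and 2 without hypoxia B.

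DNA replication genes fell almost throughout the list, with 29 of 31 lower, 0 higher and 2 not called, and 30 lower adjusted over the list alone. The cyclin gene CCNE2 fell from 1679.6 ± 249 to 174 ± 221 (log2 difference -3.81 ± 0.80 SE, adjusted p = 0.00552), the helicase subunit gene MCM5 fell from 1442 ± 169 to 196 ± 217 (log2 difference -3.21 ± 0.66 SE, adjusted p = 0.00504), the ribonucleotide reductase gene RRM2 fell from 9687 ± 612 to 1210.2 ± 737 (log2 difference -3.12 ± 0.35 SE, adjusted p = 2.85e-04), and MCM4 fell from 3621 ± 492 to 477 ± 22.7 (log2 difference -2.86 ± 0.20 SE, adjusted p = 4.79e-05). The list median was -1.91, with camera adjusted p = 8.47e-13, and adjusted p = 0.300 with an estimated correlation. Without 1 array the log2 difference of CCNE2 ranged from -5.37 to -2.26, that of MCM5 from -4.46 to -1.97 and that of RRM2 from -3.77 to -2.47, each with its lesser change when hypoxia B was left out.

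Of 30 mitosis genes, 25 fell, 0 rose and 5 were not called, and adjusted over the list alone 29 fell. The cyclin gene CCNB1 fell from 4544 ± 99.7 to 714 ± 172 (log2 difference -2.65 ± 0.21 SE, adjusted p = 6.97e-05), the kinesin gene KIF2C fell from 2424 ± 35.5 to 441 ± 176 (log2 difference -2.45 ± 0.28 SE, adjusted p = 2.98e-04), and the kinetochore gene NDC80 fell from 1814 ± 39.6 to 355 ± 97.9 (log2 difference -2.30 ± 0.26 SE, adjusted p = 2.79e-04). FOXM1, a transcription factor gene of the cell cycle, fell from 644 ± 99.2 to 99.3 ± 47.7 (log2 difference -2.49 ± 0.44 SE, adjusted p = 0.00253), a call lost without normoxia A (-2.34, adjusted p = 0.0535). Members of the list had a median log2 difference of -1.59, with camera adjusted p = 2.94e-11, and adjusted p = 0.188 with an estimated correlation.

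Of 23 DNA repair genes, 16 fell, 0 rose and 7 were not called, and adjusted over the list alone 18 fell. RAD51AP1, which acts in homologous recombination, fell from 3463 ± 485 to 259 ± 114 (log2 difference -3.68 ± 0.30 SE, adjusted p = 7.75e-05). The helicase gene BRIP1 and the exonuclease gene EXO1 had log2 differences of -2.65 ± 0.29 and -2.56 ± 0.44 SE. The DNA ligase gene LIG1 fell from 771 ± 323 to 199 ± 227 (log2 difference -2.30 ± 0.74 SE, adjusted p = 0.0367); its call was lost without normoxia A (-1.87, adjusted p = 0.154), and its log2 difference was -0.99 without hypoxia B and -3.60 without hypoxia A. The median over tested members was -1.31, with camera adjusted p = 9.01e-07, and adjusted p = 0.188 with an estimated correlation. The number that fell was 9 without normoxia A and 10 without normoxia B.

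Of 20 tested p53 targets, 11 fell, 3 rose and 6 were not called, with the same counts adjusted over the list alone. TP53INP1 fell from 4331 ± 1219 to 1107 ± 422 (log2 difference -1.97 ± 0.29 SE, adjusted p = 9.26e-04), the death receptor gene FAS fell from 1648 ± 204 to 431 ± 127 (log2 difference -1.90 ± 0.27 SE, adjusted p = 7.64e-04), the ribonucleotide reductase subunit gene RRM2B had a log2 difference of -1.81 ± 0.19 SE and ZMAT3 one of -1.67 ± 0.19 SE. The 3 that rose, named after their values were seen, were CCNG1 (0.70), GDF15 (0.62, with another probe set at 1.67) and GADD45A (0.59). The list median was -0.83, with camera adjusted p = 0.0175, and adjusted p = 0.418 with an estimated correlation. The list lost its call without normoxia B (adjusted p = 0.0643, with 7 lower) and with the filter at the 75th percentile (adjusted p = 0.0726), and without normoxia A only 1 gene rose.

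Of 17 tested interferon response genes, 11 fell, 0 rose and 6 were not called, and adjusted over the list alone 11 fell and 1 rose. IFIT1 fell from 5174 ± 867 to 238 ± 173 (log2 difference -4.48 ± 0.41 SE, adjusted p = 1.19e-04) and IFI6 fell from 7832 ± 1388 to 359 ± 103 (log2 difference -4.37 ± 0.24 SE, adjusted p = 2.40e-05). The oligoadenylate synthetase gene OAS3 fell from 1892 ± 84.9 to 156 ± 54.8 (log2 difference -3.45 ± 0.30 SE, adjusted p = 1.03e-04), with a second probe set at 0.06, and IFIT3 fell from 1440.3 ± 118 to 123 ± 81.0 (log2 difference -3.44 ± 0.41 SE, adjusted p = 3.87e-04). The median log2 difference of the list was -1.73, with camera adjusted p = 2.23e-04, and adjusted p = 0.327 with an estimated correlation. Without 1 array the log2 difference of IFIT3 ranged from -4.04 to -2.84 and that of IFIT1 from -5.21 to -3.75; without hypoxia B, 2 members of the list were called higher.

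Of 11 inflammatory and NF-kB genes, 3 rose, 1 fell and 7 were not called, with the same counts adjusted over the list alone. The chemokine gene CXCL8 rose from 288 ± 34.5 to 1626 ± 157 (log2 difference 2.40 ± 0.25 SE, adjusted p = 1.88e-04) and TNFAIP3, a gene of an NF-kB inhibitor, rose from 306 ± 20.3 to 1138 ± 230.1 (log2 difference 1.80 ± 0.27 SE, adjusted p = 0.00110). NFKBIA had a log2 difference of 0.72 ± 0.22 SE, with another probe set at 1.62, a call lost without normoxia A (0.54, adjusted p = 0.231) and a difference of 0.45 without hypoxia B. IRF1 fell, with a log2 difference of -1.12 ± 0.32 SE, a call lost without normoxia A (-1.34, adjusted p = 0.0723) or normoxia B (-0.90, adjusted p = 0.254). The list did not pass camera (median 0.42, adjusted p = 0.0957). Without hypoxia A, 5 rose and 2 fell, and the median without 1 array ranged from 0.26 to 0.69.

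Of 16 cholesterol synthesis genes, 14 rose, 1 fell and 1 was not called, with the same counts adjusted over the list alone. DHCR7, the gene of the last enzyme of the Kandutsch-Russell pathway, rose from 2003 ± 248 to 14312 ± 3269.7 (log2 difference 2.81 ± 0.20 SE, adjusted p = 5.03e-05). HMGCS1, whose product makes HMG-CoA, rose from 989.7 ± 352 to 6803 ± 3131 (log2 difference 2.72 ± 0.33 SE, adjusted p = 4.13e-04). The squalene epoxidase gene SQLE rose from 4228 ± 544 to 23682 ± 4137 (log2 difference 2.47 ± 0.19 SE, adjusted p = 6.30e-05), and MSMO1, a sterol demethylation gene, rose from 7117 ± 567 to 38211 ± 1993 (log2 difference 2.42 ± 0.17 SE, adjusted p = 4.79e-05). The gene that fell was TM7SF2 (-1.55), a sterol reductase gene, and without hypoxia A 2 genes fell. Members of the list had a median log2 difference of 2.08, with camera adjusted p = 9.85e-09, and adjusted p = 0.360 with an estimated correlation. Scaled to the hybridization controls the median was 0.64, or 2.04 above the median of all genes there, with 0 genes called higher and 1 lower.

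Of 21 serum response and immediate early genes, 16 rose, 0 fell and 5 were not called, and adjusted over the list alone 17 rose. The phosphatase gene DUSP1 rose from 993 ± 154 to 13098 ± 1170.5 (log2 difference 3.70 ± 0.18 SE, adjusted p = 1.47e-05), with 2 other probe sets at 0.06 and 2.53. The transcription factor genes FOS and FOSB rose from 485 ± 68.8 to 2899 ± 788 (log2 difference 2.503 ± 0.24 SE) and from 175 ± 55.7 to 839 ± 206 (2.13 ± 0.36 SE). ATF3, which also stands in the list of the unfolded protein response, rose from 2236 ± 90.5 to 11245 ± 43.3 (log2 difference 2.32 ± 0.16 SE, adjusted p = 4.75e-05). The list median was 1.28, or -0.17 with 1 gene called higher and 0 lower when scaled to the hybridization controls, which lay 1.23 above the median of all genes there. Camera gave adjusted p = 2.86e-09, and adjusted p = 0.188 with an estimated correlation.

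Of 16 epithelial junction and keratin genes, 7 rose, 0 fell and 9 were not called, and adjusted over the list alone 8 rose. ELF3, an epithelial transcription factor gene, rose from 1191 ± 94.6 to 5394 ± 1175 (log2 difference 2.14 ± 0.20 SE, adjusted p = 1.24e-04), although 2 other probe sets of ELF3 had log2 differences of -0.72 and -0.07. The claudin gene CLDN4 rose from 1970.0 ± 261 to 5746 ± 2836 (log2 difference 1.45 ± 0.30 SE, adjusted p = 0.00546), with another probe set at -0.47 and a difference of 0.92 without hypoxia A. The desmosome gene DSP and the E-cadherin gene CDH1 had log2 differences of 1.13 ± 0.22 and 1.02 ± 0.17 SE. Over the list the median was 0.44, or 0.20 under quantile normalization and -1.01 when scaled to the hybridization controls, where 0 genes were called higher and 3 lower, with camera adjusted p = 0.00314, and adjusted p = 0.360 with an estimated correlation. The call was also lost under quantile normalization (adjusted p = 0.0805) and scaled to the hybridization controls (adjusted p = 0.294), and the list median was 0.29 without hypoxia A, while without hypoxia B 1 gene fell. Among 10000 random lists matched on mean signal, a test chosen after seeing the data, its median lay at percentile 89.4, inside their central range of -0.46 to 0.65.

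Of 13 mesenchymal transition genes, 5 were called higher, 0 lower and 8 were not called, with 5 higher adjusted over the list alone. The integrin gene ITGA5 rose from 487 ± 26.8 to 2662 ± 33.2 (log2 difference 2.40 ± 0.20 SE, adjusted p = 8.51e-05). The repressor gene SNAI2 and the fibronectin gene FN1 rose from 65.1 ± 16.3 to 359 ± 184 and from 175 ± 2.69 to 462 ± 55.9 (log2 differences 2.03 and 1.28). The matrix metalloproteinase gene MMP2 was called as well, but its signals of 9.29 ± 1.35 in normoxia and 245 ± 31.2 in hypoxia both lay under the highest Bacillus control of the group (121 and 305), so no fold is given. MMP2, SNAI2 and FN1 each lost the call without normoxia A (adjusted p = 0.0811, 0.0578 and 0.123) and without normoxia B (0.0593, 0.0884 and 0.114), MMP2 also without hypoxia A (0.0857) and SNAI2 without hypoxia B (0.113). Other probe sets of FN1 ran from -0.94 to 2.38. The median log2 difference of the list was 0.93, or -0.26 when scaled to the hybridization controls, where 0 genes were called higher and 1 lower, with camera adjusted p = 0.0126, and adjusted p = 0.360 with an estimated correlation. Without normoxia A or without normoxia B 2 genes rose, without hypoxia A 1 gene fell, and without hypoxia B the list did not pass (adjusted p = 0.0531).

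Of 10 Wnt target and intestinal stem cell genes, 4 rose and 1 fell, with the same counts adjusted over the list alone. SOX9, a transcription factor gene of intestinal crypts, rose from 3039 ± 364 to 11711 ± 272 (log2 difference 1.94 ± 0.17 SE, adjusted p = 9.64e-05). NOTUM, the gene of a Wnt inhibitor, rose from 169 ± 69.8 to 669 ± 108 (log2 difference 1.88 ± 0.39 SE, adjusted p = 0.00518). EPHB3, an ephrin receptor gene, rose from 158 ± 147 to 573 ± 6.60 (log2 difference 2.004 ± 0.58 SE, adjusted p = 0.0248), a call lost without normoxia B (1.06, adjusted p = 0.147). The adhesion receptor gene CD44 had a log2 difference of 1.66 ± 0.17 SE, but other probe sets of CD44 ran from -1.13 to 1.86. With the probe set chosen again on the 3 arrays left, CD44 was not called without hypoxia A (0.01, adjusted p = 0.981) or hypoxia B (-0.16, adjusted p = 0.508), and under quantile normalization it was lower (-0.37, adjusted p = 0.0376). MYC fell (-1.19), and without hypoxia A 2 genes fell. The list did not pass camera (median 0.20, adjusted p = 0.126) but passed without normoxia A (median 0.47, adjusted p = 0.0297), and its median without 1 array ranged from 0.02 to 0.58. Of 8 intestinal differentiation genes 1 rose, with the same count adjusted over the list alone: the transcription factor gene KLF4, from 4807 ± 545 to 26139 ± 7689.7 (log2 difference 2.41 ± 0.22 SE, adjusted p = 1.20e-04). That list did not pass (adjusted p = 0.246), and without hypoxia A or B 2 of its genes rose, with 1 falling without hypoxia B.

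Of 23 genes of the unfolded protein and amino acid responses, 6 rose, 8 fell and 9 were not called, with the same counts adjusted over the list alone. ATF3 rose as above, EDEM1, which acts in degradation of misfolded glycoproteins, rose from 227 ± 6.54 to 983 ± 181 (log2 difference 1.998 ± 0.29 SE, adjusted p = 9.82e-04), and the chaperone gene DNAJB9 rose from 1654 ± 3.25 to 5062 ± 384 (log2 difference 1.60 ± 0.17 SE, adjusted p = 2.00e-04). SHMT2, a mitochondrial serine enzyme gene, fell from 4573 ± 437 to 1210.5 ± 105 (log2 difference -1.90 ± 0.18 SE, adjusted p = 1.27e-04). The list did not pass camera (adjusted p = 0.799); its median was -0.12 and its mean 0.03, so they differ in sign. Without normoxia A or normoxia B 3 genes fell, with a median of -0.08 and 0.03.

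Of 18 ribosome biogenesis genes, 13 fell, 1 rose and 4 were not called, and adjusted over the list alone 14 fell and 1 rose. PES1 fell from 1699 ± 98.1 to 53.4 ± 37.6 (log2 difference -4.57 ± 0.42 SE, adjusted p = 1.21e-04). POLR1A, the gene of the largest subunit of RNA polymerase I, fell from 579 ± 44.4 to 75.6 ± 86.1 (log2 difference -2.94 ± 0.68 SE, adjusted p = 0.00872), a call lost without normoxia A (-2.86, adjusted p = 0.0803) and a difference of -1.91 without hypoxia B. UTP20 fell from 528 ± 86.0 to 84.4 ± 99.3 (log2 difference -2.74 ± 0.72 SE, adjusted p = 0.0156), a call lost without normoxia A (-2.90, adjusted p = 0.0678) or normoxia B (-2.58, adjusted p = 0.111) and a difference of -1.62 without hypoxia B. RRP9 had a log2 difference of -2.21 ± 0.37 SE, and the gene that rose was NPM1 (0.72), with 2 other probe sets at -0.54 and -0.01. The list median was -0.86, with camera adjusted p = 5.84e-04, and adjusted p = 0.360 with an estimated correlation.

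Of 19 autophagy and lysosome genes, 5 rose, 5 fell and 9 were not called, with the same counts adjusted over the list alone. MAP1LC3B, the gene of an autophagosome protein, rose from 5938 ± 917 to 15198 ± 238 (log2 difference 1.36 ± 0.17 SE, adjusted p = 5.00e-04). The lysosomal genes HEXA, LAMP1 and CTSD fell, with log2 differences of -1.46 ± 0.28, -1.38 ± 0.19 and -1.20 ± 0.34 SE. HEXA lost its call without normoxia A (-1.36, adjusted p = 0.0573), and CTSD without normoxia A (-1.28, adjusted p = 0.144) or normoxia B (-1.11, adjusted p = 0.211). The list did not pass (adjusted p = 0.456), and its counts were 3 higher and 1 lower without normoxia A and 3 and 3 without normoxia B.

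**Figure D2:**
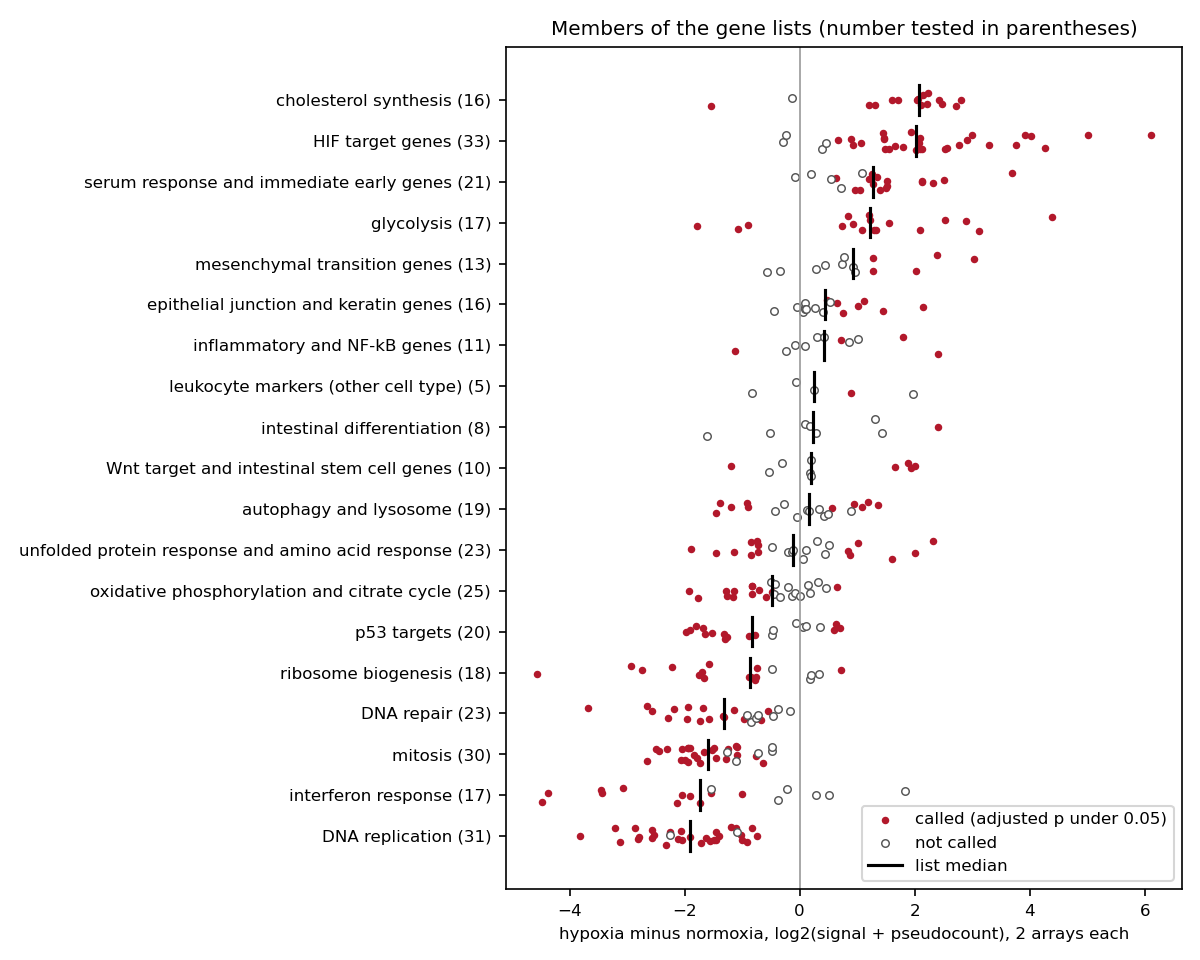
Log2 difference, hypoxia minus normoxia, of every tested member of the 19 lists with 5 or more tested members, 2 arrays per group. Filled points are called genes, open points genes that were not called and bars list medians, which run from -1.91 for DNA replication to 2.08 for cholesterol synthesis.

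Markers of cell types other than the cultured line were mostly under the signal filter. Of 4 tested fibroblast markers 1 rose (1 adjusted over the list alone), COL1A1, from 569.9 ± 35.8 to 1957 ± 289.6 (log2 difference 1.73 ± 0.22 SE, adjusted p = 4.57e-04), with 4 other probe sets from 0.32 to 0.91. Of 5 tested leukocyte markers 1 rose (1 adjusted over the list alone), the kinase gene LYN (0.89 ± 0.20 SE), a call lost without normoxia A (0.89, adjusted p = 0.0921) or normoxia B (0.89, adjusted p = 0.0908), and the list did not pass (adjusted p = 0.375). The 1 tested endothelial marker, PECAM1, was not called, with 0 called adjusted over the list alone (from 91.6 ± 17.5 to 217 ± 8.84, adjusted p = 0.173), and its means lay under the highest Bacillus control in both groups. It was called without the variance trend (adjusted p = 0.0401).

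The arrays and their control probe sets also differed between the groups, beside all of the gene groups above. The 1% brightest probe sets held 24.9% and 29.9% of all signal on normoxia A and B and 39.2% and 38.5% on hypoxia A and B. The 18 hybridization control probe sets, which read RNA added before hybridization, had geometric means of 2444 and 4595 in normoxia and 9869 and 8594 in hypoxia, and all 18 were higher in hypoxia within both letters. The Bacillus control probe sets had medians of 16.9 and 17.2 in normoxia and 55.5 and 25.7 in hypoxia. Of 3 transcripts with control probe sets at both ends, the 5' to 3' signal ratio of ACTB was 0.796 and 0.784 in normoxia and 0.604 and 0.565 in hypoxia. The ratio of GAPDH was 1.09 and 1.00 against 1.096 and 1.05, and that of HUMISGF3A 0.276 and 0.245 against 0.310 and 0.408. The median SD within a group on the log2 scale was 0.15 in normoxia and 0.27 in hypoxia, and across genes the arrays correlated at 0.967 within normoxia, 0.913 within hypoxia and 0.790 to 0.824 between the groups. Genes are not independent replicates.

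**Figure D3:**
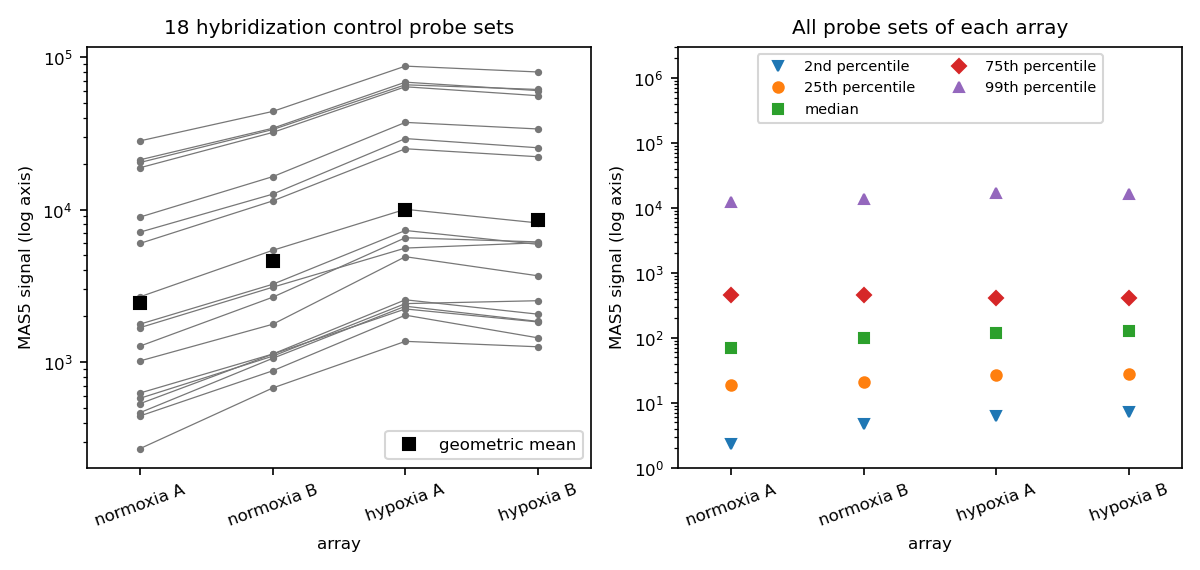
MAS5 signal (log axes) on each of the 4 arrays: on the left the 18 hybridization control probe sets (lines) with their geometric mean (squares), on the right percentiles of all probe sets. The control means are 2444 and 4595 on the normoxia arrays and 9869 and 8594 on the hypoxia arrays, and the medians of all probe sets are 69.2 and 99.96 in normoxia and 119.6 and 124.97 in hypoxia.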

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

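The tests of the brightness of the control probe sets were chosen after the values had been seen. The hybridization controls were 4.04 times as bright on hypoxia A as on normoxia A, and 1.87 times as bright on hypoxia B as on normoxia B. The letters are not known to mark pairs, and the normoxia arrays differed widely from each other, with geometric means of 2444 and 4595. Both hypoxia means, 9869 and 8594, lay above these. The Bacillus controls, which lie outside the gene comparison, had medians 3.28 and 1.49 times as high on hypoxia A and B as on the normoxia arrays of the same letter.

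A candidate explanation for the brighter controls is a larger scale factor on the hypoxia arrays, which would raise the floor of an array with the controls. The 2nd percentile of signal was 2.76 times as high on hypoxia A and 1.55 times as high on hypoxia B as on normoxia, and both ratios passed the bound of 1.1. That bound was set after the values were seen, so passing it is no support. The 2nd percentile also differed within normoxia (2.28 on A, 4.62 on B). The 25th percentile rose less than the controls, from 18.7 to 26.4 on the A arrays and from 21.2 to 27.9 on the B arrays. The floor therefore does not settle the explanation. Under quantile normalization 88.2% of the called genes kept their call and sign. This argues against a brightness difference that depends on signal level alone as the source of most called genes. Quantile normalization gives every array the same distribution, so it cannot test a shift shared by most genes. Whether the amount of cellular RNA signal per array differed for a technical reason, such as labelling, or because the cells held less mRNA per unit of total RNA was not tested and stays open. Scaled to the controls, 52 genes were higher and 5514 lower. This scaling moves all genes of an array together, and the control means of the 2 normoxia arrays differed (2444 and 4595). It thus adds a spread shared by all genes, and the fit there took each variance from the intensity trend alone. The 52 and 5514 rest largely on a shift between arrays and are not separate results of single genes. The same holds for the counts of list members under that scaling. Of the 4803 called genes, 61.0% kept their call and sign there, and 1238 changed sign.

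The 18S ribosomal RNA probe sets were 2.81 times as bright on hypoxia B as on normoxia B, and 0.607 times as bright on hypoxia A as on normoxia A. Among 3006 probe sets past the filter that have no gene name here, 550 were called, 307 higher and 243 lower.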

How the results depend on the processing

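Settings with the probe sets chosen again, with the hybridization controls or with quantile normalization and a block were chosen after seeing the data. For the named genes, 1204 of the comparisons fixed beforehand with an alternative kept direction and side of the threshold, 55 lost the call, 2 gained one and 1 changed sign; for the lists the numbers were 281, 17, 2 and 1, the last a change of camera's direction. The counts of changed, higher and lower genes moved to 8409, 3739 and 4670 with all probe sets tested (27307 tested) and to 3141, 1330 and 1811 without the variance trend. With a 2-fold threshold 1221 were higher. Scaling to the hybridization controls gave 52 higher and 5514 lower, or 52 and 5791 with the probe sets chosen again. Leaving out 1 array, with the probe sets held or chosen again, gave 2575 to 6257 changed genes, 1204 to 2510 higher and 1371 to 3749 lower; a lone array was assumed to vary like the other group. None of the 13 lists passed with an estimated correlation (0 lists), a test with little power on so few arrays. For the list of the unfolded protein response, not called, camera's direction changed without a filter, where the median was -0.13. The median itself changed sign without normoxia B (0.03) and scaled to the 75th percentile (0.02). Under settings fixed beforehand the medians of 3 other lists that were not called also changed sign, that of intestinal differentiation without normoxia A (-0.08), that of autophagy and lysosome without hypoxia B (-0.09) and that of the leukocyte markers without normoxia A (-0.12) and under quantile normalization (-0.18). Scaled to the hybridization controls, the medians of the 19 lists tested lay below 0 except those of the HIF targets (0.57) and cholesterol synthesis (0.64), and those of the Wnt targets and the inflammatory genes, not called, moved to -1.22 and -0.92. Without the variance trend the calls of LIG1, HIF1A, CLDN4, DTL, BNIP3, MCM5, CCNE2, EPHB3, DSP, NFKBIA, IRF1, UTP20, POLR1A and LYN were lost (adjusted p = 0.0562 to 0.153). Without a filter LIG1, HIF1A, SNAI2, FN1 and CTSD lost theirs (adjusted p = 0.0565 to 0.0695). With the mean of a gene's probe sets the calls lost were those of MMP2, FN1, HK2, ELF3, CLDN4 and COL1A1 (adjusted p = 0.0629 to 0.176). LIG1 lost its call under quantile normalization (adjusted p = 0.0635), and MMP2 with a pseudocount of 1 (0.0628), while PECAM1 gained one without the variance trend (0.0401). With the probe sets chosen again, calls kept with them held were lost by LOC103344931 (adjusted p = 0.0545) and the mesenchymal list (0.0532) without normoxia A and by MMP2 (0.0751) and NFKBIA (0.0589) without hypoxia B. Further genes of the report had other probe sets of the same sign but with log2 differences over 1.5 times apart. Such probe sets were found for IL1RAP (2.07), SLC43A3 (-2.87), EGLN3 (2.17), EPAS1 (0.88), MMP2 (0.93), MCM5 (-1.35) and PFKL (-0.67). They were also found among the several other probe sets of SDHC (-1.65 to -0.38), ZMAT3 (-3.09 to -0.97), ATF3 (1.06 to 2.34), POLR1A (-2.67 to -1.02) and TPI1 (-1.59 to -0.62). PDK1, not called, ran from -0.33 to 1.12 without 1 array. CD44 changed to -0.37 (adjusted p = 0.0376) under quantile normalization with the probe sets chosen again, and without 1 array in that way ran from -0.16 to 1.69, against 1.56 to 1.77 with the probe set held, because another probe set of the gene was taken. For the other changes the cause was not tested, except that fewer arrays and more probe sets entered where named. The adjusted p of CD44 over its alternatives ran from 1.44e-14 to 0.981. The labels give exp A and exp B in both groups without stating a shared day or culture. The deviations of same-letter arrays correlated at 0.09 across genes. With a replicate block 5487 genes were called, 2222 higher and 3265 lower, and with quantile normalization as well 5236. The block alone changed no call of a named gene or list. Low signal limits the folds of the 783 lower and 143 higher genes whose dimmer group lay under the highest Bacillus control. That control was 305 in hypoxia and 121 in normoxia, so the 2 counts cannot be compared with each other.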

Other observations

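Of the tests in this part, those of the interferon and cholesterol lists under quantile normalization and against random lists were chosen after the results had been seen, as were the 10 further gene groups themselves; the bounds for the second interferon list and the fatty acid list were set before their values were seen. Percentiles are those of a list's median among the medians of 10000 random lists of the same size matched on mean signal, and describe these arrays.

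Genes of mitochondrial ribosomal proteins were lower in hypoxia, with 55 of 75 falling, 3 rising and 17 not called (median -1.07, percentile 0; 34 fell without normoxia B). MRPL20 fell from 4328 ± 651 to 648 ± 59.4 and MRPL24 fell from 1858 ± 6.87 to 309 ± 44.8. Of 33 proteasome subunit genes 22 fell, 1 rose and 10 were not called (median -0.73, percentile 0), among them PSMA3, which fell from 10042 ± 864 to 2162 ± 810.0, although another probe set of PSMA3 had a log2 difference of 2.01. Of 17 aminoacyl-tRNA synthetase genes 9 fell, 1 rose and 7 were not called (median -0.62, percentile 0.690), with LARS1 falling from 6808 ± 365 to 1914 ± 249.6. Of 15 histone lysine demethylase genes 5 rose and 0 fell (median 0.49, percentile 98.0; 2 rose without normoxia B, with a median of 0.30), with KDM7A rising from 399.8 ± 64.0 to 2448 ± 339. Of 16 genes of MAP kinase phosphatases and growth factor ligands 8 rose and 0 fell (median 0.90, percentile 99.9; 5 rose without normoxia B), with DUSP16 rising from 250.2 ± 8.28 to 2034 ± 629 and HBEGF from 1046 ± 141 to 4105 ± 1620.4.

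Cytosolic ribosomal protein genes had 51 of 57 members called higher and 2 lower (median 0.95, percentile 100), but under quantile normalization the median was -0.02, with 3 higher and 4 lower, so their direction depends on the scaling. Without hypoxia A 24 were higher and without hypoxia B 27. Of 329 zinc finger genes 18 rose and 48 fell (median -0.19, percentile 5.72), and of 236 solute carrier genes 34 rose and 56 fell (median -0.07, percentile 28.1). The number that fell in these 2 families was 11 and 20 without normoxia A, 16 and 29 without normoxia B, 81 and 77 without hypoxia A and 83 and 71 without hypoxia B. The number that rose was 9 and 18, 5 and 21, 27 and 49, and 25 and 41 in the same order. The median of the solute carriers was -0.18 without normoxia A, 0.04 without normoxia B, -0.12 without hypoxia B and 0.07 scaled to the 75th percentile, so its sign is not settled. That of the zinc finger genes was -0.09 without hypoxia A, -0.12 without hypoxia B and -0.05 scaled to the 75th percentile. Unless another scaling is named, list medians in this and the preceding paragraph are on the deposited scale. Scaled to the hybridization controls, the medians of the histone demethylase, phosphatase and cytosolic ribosomal protein groups were -0.89, -0.52 and -0.51, with 0 genes called higher in each and 2, 1 and 5 lower, each above the median of all genes there (-1.40). Under that scaling the zinc finger and solute carrier families had medians of -1.51 and -1.40, with 0 and 1 genes called higher and 154 and 107 lower.

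Interferon response genes had a median of -1.73. A difference between arrays that depends on signal level alone is argued against by the median under quantile normalization, -1.79. A general fall of genes at these signal levels is argued against by the list's percentile, 0. Neither value tests a shift shared by most genes. Scaled to the hybridization controls the list median was -3.18, against -1.40 for all genes. A second list of 25 tested interferon-inducible genes, with no member in the first, had 15 lower, 0 higher and a median of -1.43 (percentile 0), which is consistent with a fall of interferon-inducible genes beyond the fixed list; it included DDX60, from 2155 ± 131 to 229 ± 12.8, and without normoxia B 3 of its genes were called higher. Genes of this kind seen among the largest decreases had been left out of the second list. That the fall belongs to hypoxia is a hypothesis, since a difference between cultures other than oxygen was not tested.

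Cholesterol synthesis genes had a median of 2.08, which was 1.99 under quantile normalization and at percentile 100. Both values argue against a difference that depends on signal level alone or a general rise at these signal levels. Neither value tests a shift shared by most genes. A rise of sterol-regulated lipid synthesis may include fatty acid synthesis, where 7 of 12 genes rose, 2 fell and 3 were not called; ACSS2 and INSIG1, seen among the raised genes beforehand, had been left out of that list. SCD rose from 15116 ± 974 to 46457 ± 3994 and FASN from 3796 ± 507 to 12642 ± 3733, while FABP5 fell from 19146 ± 1729 to 6988 ± 1688. The median of 0.74 lay just past the bound of 0.73, at percentile 97.71, within 2 Monte Carlo standard errors of the bound, a margin set after the value was seen, and leaves this open. The number of its genes that fell was 1 without normoxia A or normoxia B, and scaled to the hybridization controls the medians of the cholesterol and fatty acid lists were 0.64 and -0.71, with 0 genes called higher in each.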
